A study of Mus musculus with 2 samples.

How the data were processed

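H3K4me3 was measured by chromatin immunoprecipitation and sequencing in liver pools of newborn mice, as 2 biological replicates of 1 group, per the labels. Replicate 1 was a pool of 15 mice. The authors deposited 4 narrowPeak lists on assembly mm10: 1 for each replicate, 1 for both replicates pooled and 1 of replicated peaks. Per the file headers, each replicate's list and the pooled list were derived from alignments and a control, and the replicated list from the pooled list and the lists of both replicates. The peak caller, its version and its thresholds are not given in the sources used here. The control and the signal tracks were not analysed here.

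The deposited fold is a ratio of enrichment at the peak summit. Tested on the values, it equals reads plus 1 over background plus 1, because the fold and the −log10 p together solved to a whole number of reads and a Poisson background at 100% of peaks in every list, within a tolerance of 0.001 of −log10 p. The deposited −log10 p and −log10 q are those of the caller, and the smallest −log10 p was 2.01 in replicate 1 and 2.02 in replicate 2. The deposited score column was not used. The lists hold weak peaks: 972 peaks of replicate 1, 1298 of replicate 2, 527 of the pooled list and 13 of the replicated list had a q above 0.05. The most common background was 1.96 reads in replicate 1, 1.72 in replicate 2 and 3.59 in the pooled list. The size of the libraries is unknown. The number of reads at the summit limits the precision of each fold, and weak peaks rest on about 10 reads. Because peaks were called separately in each list, levels were not compared between lists, and the replicates were compared by overlap and by correlation over shared peaks.

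Annotation was GENCODE M21 on GRCm38, the assembly also called mm10, and no peak lay past the end of a chromosome of the reference. It gave 21911 protein-coding genes on chromosomes 1 to 19, X and Y, with 93477 transcript starts. A gene was called marked if a peak overlapped by at least 1 bp a window of 1 kb on each side of any of its starts. Domains were replicated peaks merged over gaps of up to 1 kb, and the width of a gene is that of its widest domain at a promoter. CpG content is the observed to expected ratio within 500 bp on each side of the outermost start, split into tertiles. The fold of a gene is that of its strongest peak at any of its starts. That start can differ in CpG content from the outermost start, on which lists were matched. Peak sharing and genomic places were set against 100 random placements on the same chromosome. The 25 gene lists, the rule for named genes and the alternatives named here were fixed before the data were examined. A total of 1 listed symbol, Ahsp, had no match in the annotation. Marked shares were tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 25 lists. Genes are the units of these tests, so p-values say nothing about the spread between animals. Marked shares were also set against 10000 random lists of protein-coding genes with the same number per CpG tertile. The lowest tertile of 7304 genes holds 1117 olfactory receptor genes, and no such lists were drawn without them. Median widths were placed among 10000 random lists of marked genes with the same number per CpG tertile, and a list was called wide or narrow in the outer 2.5% at either end.

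The rule for the genes named in the text takes the 3 marked members with the highest fold and up to 3 unmarked members in alphabetical order of each list, the 10 genes with the widest domain, the 10 with the highest fold, the 5 strongest promoters specific to each replicate, and Alb, Afp, Hnf4a, Gata1, Klf1 and Cyp7a1. The text names a part of these. Alternatives were windows of 500 and 2500 bp, −log10 q of at least 2 or 5, the outermost start, each replicate alone, the pooled list, an overlap of 50% of the peak, other merging gaps, another background and another CpG window. Sequence uniqueness is the share of 31-mers within 1 kb of the outermost start that occur once in the genome. The read length is not given in the sources used here, so this only approximates what the authors' alignment could place.

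Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with fixed seeds. The functions were tested on simulated data. Of the 30682 replicate 1 peaks compared with a copy that kept 80% in place, 79.5% were found shared. The right number of reads was found at 100% of 19829 simulated peaks, and 0.197% of them solved within the tolerance once p had been moved by up to 10%. Of 1500 random lists 2% were called, and of 1000 wholly marked lists 100%, among 21911 genes. Widths multiplied by 2 were called wide in 100% of simulated lists and unchanged widths in 0%, among 14546 marked genes.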

Results

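Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in the liver of newborn mice (postnatal day 0). The series held 2 biological replicates of 1 group and no second condition. Replicate 1 was a pool of 15 mice and replicate 2 a pool of mice whose number the labels do not give, each of mixed sex. Peak lists were given for each replicate, for both replicates pooled and for the replicated peaks, and positions are on mm10. Replicate 1 had 30693 peaks and replicate 2 had 32402 (mean 31547.5 ± 1208, SD, n = 2). The pooled list had 31667 peaks and the replicated list 24101. The number of reads per library is unknown, so depth was read only at the peak summits, where the median was 22 reads in replicate 1, 18 in replicate 2 and 35 in the pooled list.

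The labels imply a comparison between the replicates, which asks how far separate pools of newborn livers carry the mark at the same places. In replicate 1, 83.7% of the 30682 peaks on chromosomes overlapped a replicate 2 peak by at least 1 bp, against a mean of 3.02% and a maximum of 3.28% over 100 random placements of the replicate 2 peaks. In replicate 2, 81.4% of the 32391 peaks overlapped a replicate 1 peak, against a mean of 2.85% for random placement. Sharing depended on enrichment. In the lowest decile of fold enrichment 45.7% of replicate 1 peaks and 36.6% of replicate 2 peaks were shared, and in each of the 4 highest deciles 100% were. Unshared peaks of replicate 1 had a median fold of 3.35, a median width of 259 bp and 10 reads at the summit, while its shared peaks had 10.5, 1081 bp and 34 reads. Fold enrichment at the 25682 shared peaks correlated between the replicates with Pearson's r = 0.867 on the log2 scale and Spearman's rho = 0.845, across peaks, which are not independent replicates. The fold values are the authors'. They were used to describe and rank peaks and to compare gene lists within 1 peak list, and between the replicates only in this correlation.

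**Figure D1:**
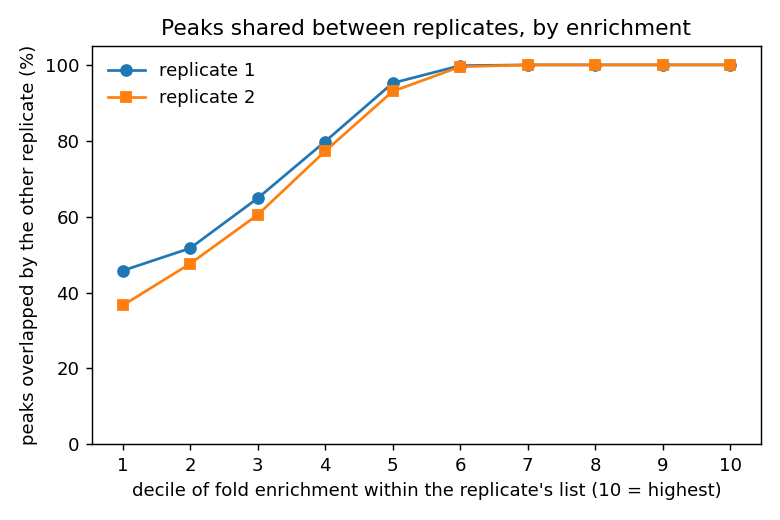
Share of each replicate's peaks (%, vertical axis) that overlapped a peak of the other replicate, by decile of fold enrichment within the replicate's own list (horizontal axis, 10 the highest). The share lies at 45.7% (replicate 1) and 36.6% (replicate 2) in the lowest decile and at 100% in the 4 highest.

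All 24101 replicated peaks were also in the pooled list, with identical coordinates, and made up 76.1% of it. Replicated peaks had a median fold of 13.0 and a median width of 1303 bp. The 7566 pooled peaks left out of the replicated list had a median fold of 2.97 and a median width of 254 bp. Of the replicated peaks, 96.4% overlapped peaks of both replicates, against 1.51% of those left out. The replicated list was derived with the lists of both replicates, so this contrast is largely built in. At a protein-coding promoter lay 65.2% of the replicated peaks, against 22.5% of those left out.

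The next comparison asks where in the genome the replicated peaks lay. Of 24091 replicated peaks on chromosomes, 65.3% fell within 1 kb of an annotated start of a protein-coding gene, against a mean of 6.41% over 100 random placements. A further 3.63% lay at the start of a long non-coding RNA, 1.57% at the start of another annotated gene and 3.25% in an exon. Another 12.7% lay in an intron of a protein-coding gene and 13.6% elsewhere, which can include introns of non-coding genes. Promoter peaks were stronger and wider than the rest: the median fold was 27.1 and the median width 1811 bp, against 4.36 and 558 bp in these introns and 5.45 and 625 bp elsewhere.

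A replicated peak lay within 1 kb of a start of 14546 of 21911 protein-coding genes (66.4%), called marked genes from here on. The replicates taken alone gave 14755 and 14729 genes (mean 14742 ± 18.4, SD, n = 2), of which 14504 were common to both. The highest promoter fold was 86.5, at the shared promoter peak of Dido1 and Gid8 on chromosome 2. It was followed by Hsp90ab1, a cytosolic chaperone (85.9), the kinase gene Abl1 (83.1), U2surp (82.6), Ywhaz, a 14-3-3 protein (82.0), Dnttip2, the peroxisome assembly gene Pex6 and the mTORC1 component Rptor (each 81.7) and the cytokine signalling kinase Jak1 (81.5). Of the marked genes, 2978 (20.5%) shared their strongest peak with another gene, so that the peak could not be assigned to either.

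All members of the plasma protein and hepatocyte transcription factor lists were marked, while adult-type hepatocyte genes were marked in part. All 24 plasma protein genes had a replicated promoter peak, against 66.3% of other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 25 lists, adjusted p = 0.000469). All 20 hepatocyte transcription factors did too (Fisher's exact, adjusted p = 0.00128). Among plasma proteins the fold was highest at Apoh (36.0, at a peak shared with another gene), Apob, the structural protein of very low density lipoprotein (22.3), and Trf, transferrin (20.3, a shared peak). The shared Apoh peak lay at chromosome 11, 108342220 to 108344704. The widest domain of Apoh lay apart from it, at 108395175 to 108398008, and was shared with no other gene. The rank of Apoh therefore rests on a peak that may belong to the other gene. Alb, serum albumin, had a fold of 5.91 in a domain of 2390 bp at chromosome 5, 90460930 to 90463319, inside the gene and just downstream of its outermost start. Among the transcription factors Foxa3 reached 72.6, at a peak shared with Sympk, Xbp1 64.6 and Rxra 52.3, and Hnf4a had 14.2 in a domain of 3494 bp at chromosome 2, 163547079 to 163550572, at a start inside the gene.

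**Figure D2:**
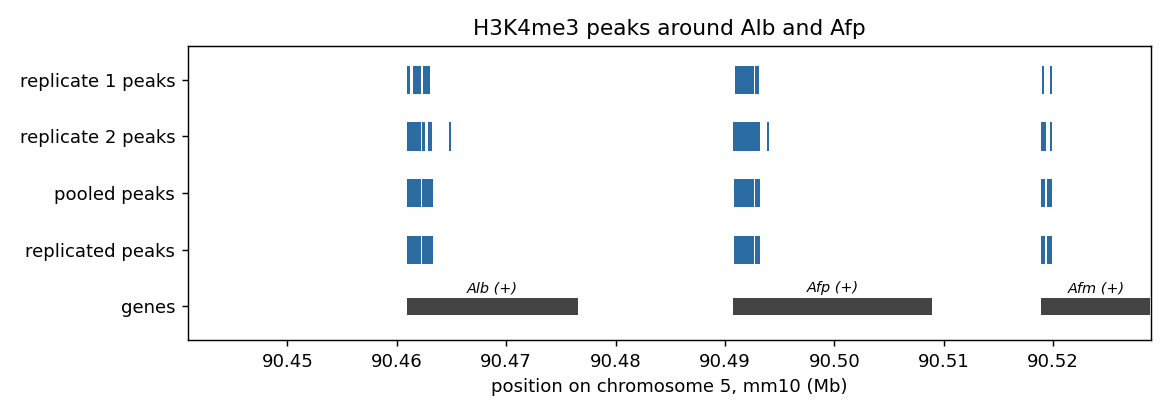
Map of the region of Alb, Afp and Afm on chromosome 5 (horizontal axis, Mb on mm10), with protein-coding genes as dark bars and peaks of each list as blue bars. Each list holds peaks at the starts of Alb and Afp, where the replicated peaks had folds of 5.91 and 5.75.

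Metabolic pathways of the liver were also marked throughout. This held for all 17 genes of the urea cycle and gluconeogenesis (Fisher's exact, adjusted p = 0.00253), all 18 of fatty acid oxidation and ketogenesis (adjusted p = 0.00178) and all 18 of cholesterol and fatty acid synthesis (adjusted p = 0.00178). Pcx, pyruvate carboxylase, had a fold of 55.4, Acsl1, which activates long-chain fatty acids, 65.0, and Hmgcr, the rate-limiting enzyme of cholesterol synthesis, 56.6. All 17 fetal liver and oncofetal genes were marked (Fisher's exact, adjusted p = 0.00253), among them Igf2bp3 (37.4), Lin28b (37.3) and Afp, alpha-fetoprotein (5.75, domain of 2334 bp at chromosome 5, 90490856 to 90493189, inside the gene). Of these calls, 3 were lost under an alternative: fetal genes at the outermost start only (Fisher's exact, adjusted p = 0.0737), fatty acid oxidation when peaks shared between genes were not counted (adjusted p = 0.0790), and both fatty acid oxidation and the urea cycle among genes with mostly unique sequence (adjusted p = 0.0577 for each). In that last setting all 15 remaining genes of each list were marked, and the share of other genes rose from 66.4% to 75.4%. With the same CpG content, random lists were marked at a mean of 55.6% for the urea cycle and 74.7% for fatty acid oxidation. For cholesterol and fatty acid synthesis the mean was 86.4%, and for fetal genes 75.6%. In that order, the shares of 100% stood at percentiles 100, 99.9, 98.2 and 99.9.

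Adult-type hepatocyte genes and acute phase genes were marked in part. Of 26 adult-type genes 18 were marked (69.2%, Fisher's exact, adjusted p = 0.873), with Glul, glutamine synthetase, at 52.1 (a shared peak), Oat at 33.9 and Gls2 at 24.9. The median fold of the marked members was 7.35, against 20.6 in random lists of marked genes with the same CpG content (percentile 0.04). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a fold of 5.95 in a domain of 2902 bp at chromosome 4, 6272813 to 6275714, over its start. Cyp1a2, Cyp2a5 and Cyp2c29, drug-metabolizing cytochromes, had no replicated promoter peak. Of 17 acute phase genes 12 were marked (70.6%, Fisher's exact, adjusted p = 0.873), including Hp, haptoglobin (19.9), Cd14 (19.1) and Itih3 (14.5), and Orm1, Orm2 and Orm3 were not. Orm1 had a weak promoter peak in replicate 2 (2.95). Around the starts of Cyp2a5 and Cyp2c29 33.7% and 7.51% of 31-mers were unique in the genome, so the state of these genes is uncertain, while Cyp1a2 had 94.6%. Against random lists with the same CpG content, in which 40.9% and 28.7% of genes were marked, the shares of both lists stood at the 99.9th and 100th percentile. The lowest CpG tertile behind these random lists includes the olfactory receptor genes, almost all unmarked. Among genes with at least 90% unique 31-mers, 15 of 18 adult-type (83.3%) and 12 of 13 acute phase genes (92.3%) were marked. Neither share passed against the other genes of this kind (75.5% marked, Fisher's exact, adjusted p = 0.639 and 0.274).

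Among lists of blood-forming lineages the marked share lay between 50% and 100%. All 23 erythroid genes found in the annotation were marked (Fisher's exact, adjusted p = 0.000716), with Urod, of haem synthesis, at 70.3 (a shared peak), Klf1, an erythroid transcription factor, at 53.7, and Tfrc, the transferrin receptor, at 47.1. Klf1 lay in a domain of 3918 bp at chromosome 8, 84900778 to 84904695, over its start, and Gata1 had a fold of 24.6 in a domain of 4633 bp at chromosome X, 7964030 to 7968662, at a start inside the gene. Of 18 stem and progenitor genes 17 were marked (Fisher's exact, adjusted p = 0.0188), with Kit at 37.1, Ikzf1 at 36.0 and Lmo2 at 35.3, and Mpl, the thrombopoietin receptor, was not. This call was lost when olfactory and vomeronasal receptor genes were left out of the background (Fisher's exact, adjusted p = 0.0626) and among genes with mostly unique sequence (adjusted p = 0.142). In these settings the share of other genes was higher, 71.1% and 75.5% against 66.4%. For the other blood lists the share did not pass the test: 8 of 16 megakaryocyte genes (Fisher's exact, adjusted p = 0.262), 11 of 20 macrophage and Kupffer cell genes (adjusted p = 0.429), 12 of 17 granulocyte genes (adjusted p = 0.873) and 12 of 20 lymphoid genes (adjusted p = 0.758). The strongest marked members were, in that order, Nbeal2 (43.8), Tyrobp (11.3), Prtn3 (25.6, a shared peak) and Vpreb1 (48.4, a peak shared with Top3b). The median folds of marked members were lower, at 10.98 (megakaryocyte), 4.63 (macrophage), 7.19 (granulocyte) and 7.52 (lymphoid). Random lists of marked genes with the same CpG content had 23.5, 13.3, 16.3 and 18.5 (percentiles 4.98, 0.04, 1.44 and 1.015). Gp1ba, Cd163, Elane and Cd4 were among the unmarked. Of these, Gp1ba had a weak promoter peak in replicate 2 (4.05) and Elane in replicate 1 (3.04). Set against random lists with the same CpG content instead of all other genes, the macrophage share (55% against a mean of 21.9%, percentile 99.9), the granulocyte share (70.6% against 29.6%, percentile 100) and the lymphoid share (60% against 37.3%, percentile 99.1) were high, and the megakaryocyte share was not (50% against 44.3%, percentile 70.9). The lowest CpG tertile behind these lists includes the olfactory receptor genes, almost all unmarked, which lowers the means. Among genes with at least 90% unique 31-mers, without CpG matching, the shares were 52.9% (macrophage), 76.9% (granulocyte) and 60% (lymphoid). The share of other genes was then 75.5%, so a high share depends on the comparison.

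The remaining lists covered other cells of the liver, other tissues and broadly used genes. Endothelial genes (17 of 20, Fisher's exact, adjusted p = 0.152), stellate cell and fibroblast genes (16 of 20, adjusted p = 0.318) and cholangiocyte genes (15 of 18, adjusted p = 0.210) did not pass the test. Kdr, a vascular growth factor receptor, had a fold of 25.1, Reln 40.9 and Notch2 50.2, while Tie1, Col3a1 and Krt7 were unmarked. Tie1 and Col3a1 had weak promoter peaks in replicate 2 (3.81 and 3.55) and in the pooled list. The median folds of marked members were 7.63 (endothelial), 8.17 (stellate) and 18.4 (cholangiocyte). Random lists of marked genes with the same CpG content had 22.1, 25.9 and 31.8 (percentiles 0.175, 0.09 and 3.62). Against random lists with the same CpG content the endothelial share (85% against a mean of 53.3%, percentile 100) and the stellate share (80% against 60.0%, percentile 99.1) were high, and the cholangiocyte share was at percentile 90.1 (83.3% against 72.8%). These random lists too drew on the lowest CpG tertile with its olfactory receptor genes. The endothelial share passed without replicate 2 (Fisher's exact, adjusted p = 0.0487), with the 2500 bp window (adjusted p = 0.0485) and in the pooled list (adjusted p = 0.0118), and the stellate share in the pooled list (adjusted p = 0.0477). When peaks shared between genes were not counted, the endothelial, stellate and patterning shares passed as well (Fisher's exact, adjusted p = 0.0123, 0.0393 and 0.00163). Their marked members did not change (17 of 20, 16 of 20 and 27 of 32), while the share of other genes fell from 66.4% to 54.1%. Neuron genes (13 of 20, Fisher's exact, adjusted p = 1) and developmental patterning regulators (27 of 32, adjusted p = 0.0628) did not pass either. The patterning share was 93.8% without replicate 2 (Fisher's exact, adjusted p = 0.00139), 87.5% with the 2500 bp window (adjusted p = 0.0224) and 96.9% in the pooled list (adjusted p = 0.000495). Against random lists with the same CpG content, however, neither the patterning share (84.4% against a mean of 87.4%, percentile 29.2) nor the neuron share (65% against 73.2%, percentile 15.7) was high. Slc17a7 (14.6), Elavl3 (8.50), Gsc (21.1) and Dlx1 (17.8) were marked, and Neurod1 and Pax7 were not. Both Neurod1 and Pax7 had weak promoter peaks in replicate 1 (3.38 and 4.05). Muscle genes were marked less often than other genes (2 of 19, Fisher's exact, adjusted p = 5.87e-06), as were gut and pancreas genes (3 of 20, adjusted p = 2.01e-05) and germline genes (2 of 20, adjusted p = 3.27e-06). The exceptions were Ckm (a peak shared with Klc3) and Ryr1, Lgr5, Cdx2 and Pdx1, and Tex14 (a peak shared with Rad51c) and Dazl. Only 3 of 1134 olfactory receptor genes were marked, Olfr56 (a peak shared with Ifi47), Olfr94 and Olfr1033, and the p lay below the smallest number the software holds. All 20 cell cycle genes and all 20 housekeeping genes were marked (Fisher's exact, adjusted p = 0.00128 for each), with Mki67 at 68.2 and Actb at 69.0. Random lists with the same CpG content were already marked at a mean of 94.5% for the cell cycle list, which stood at percentile 84.8, and at 84.9% for the housekeeping list, which stood at percentile 99.6.

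**Figure D3:**
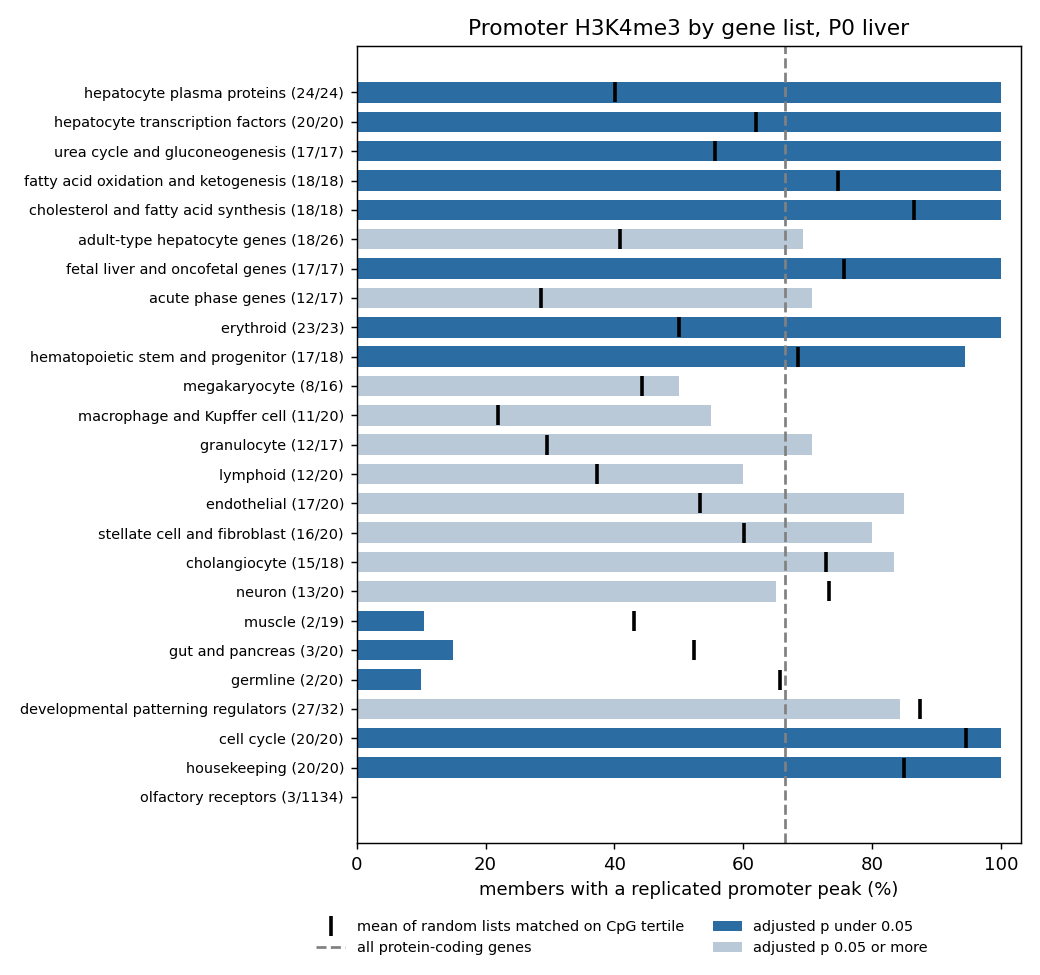
Share of the members of each gene list with a replicated promoter peak (%, horizontal axis), with marked and total members beside the name and dark bars for an adjusted p under 0.05. The black ticks are the mean of random lists matched on CpG tertile and the dashed line is all protein-coding genes (66.4%). The olfactory receptor list had 3 of 1134 genes and no matched lists were drawn for it.

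Domain width asks at which promoters the mark spreads. Replicated peaks within 1 kb of each other were merged into 20948 domains, and the widest domain at a marked gene had a median of 2170 bp, a 90th percentile of 4208 bp and a maximum of 13372 bp. The widest lay at Kdm6b, an H3K27 demethylase (chromosome 11, 69408053 to 69421424; 12727 bp in replicate 1 and 13311 bp in replicate 2). It was followed by Gtpbp1 and Josd1, which share a domain of 13228 bp, Irf2bp2 (12986 bp), the transcription factor gene Klf3 (12589 bp), Zbtb7b (12048 bp), Sdc4 (11824 bp), Dhrs11 and Mrm1 in 1 domain (11643 bp) and the erythrocyte ankyrin gene Ank1 (11584 bp). Some of these were narrower in a replicate's own list, with 7015 and 7360 bp at Klf3, 6172 bp in replicate 2 at Sdc4 and 7140 bp in replicate 1 at Ank1. Erythroid genes had a median width of 5847 bp, hepatocyte transcription factors 4594 bp, stem and progenitor genes 4595 bp and fetal genes 3688 bp, each at the 100th percentile of 10000 random lists of marked genes matched on CpG content. Plasma proteins (3052 bp, percentile 99.8), urea cycle (3366 bp, 99.9), fatty acid oxidation (3033 bp, 99.7), lipid synthesis (2912 bp, 98.0), cell cycle (3426 bp, 99.8) and housekeeping genes (3311 bp, 99.9) were wide as well. Neuron genes (790 bp, percentile 0) and patterning regulators (1528 bp, percentile 0.09) were narrow. The patterning percentile was 65.4 when peaks up to 3 kb apart were merged, and 3.87 without replicate 2, and that of lipid synthesis was 94.3 with the same 3 kb gap. Within the limits of 2.5% at either end lay adult-type (2121 bp, percentile 72.3), acute phase (2407 bp, 88.3), megakaryocyte (1278 bp, 4.03), macrophage (1279 bp, 6.89), granulocyte (2807 bp, 96.0), lymphoid (1834 bp, 40.2), endothelial (2221 bp, 75.6), stellate (2095 bp, 59.2), cholangiocyte (2061 bp, 45.5), gut and pancreas (852 bp, 3.38) and olfactory receptor genes (827 bp, 5.1). Of these, granulocyte genes were wide without replicate 2 (percentile 97.6) and endothelial genes with the 3 kb gap (97.7), and gut and pancreas genes were narrow without replicate 2 (0.755) but not without replicate 1 (65.3). Olfactory receptor genes were narrow without replicate 1 (0.38) or replicate 2 (1.58). Macrophage genes were narrow with no merging (0.06) and at percentile 51.8 without replicate 2. Muscle and germline genes had too few marked members for a width.

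**Figure D4:**
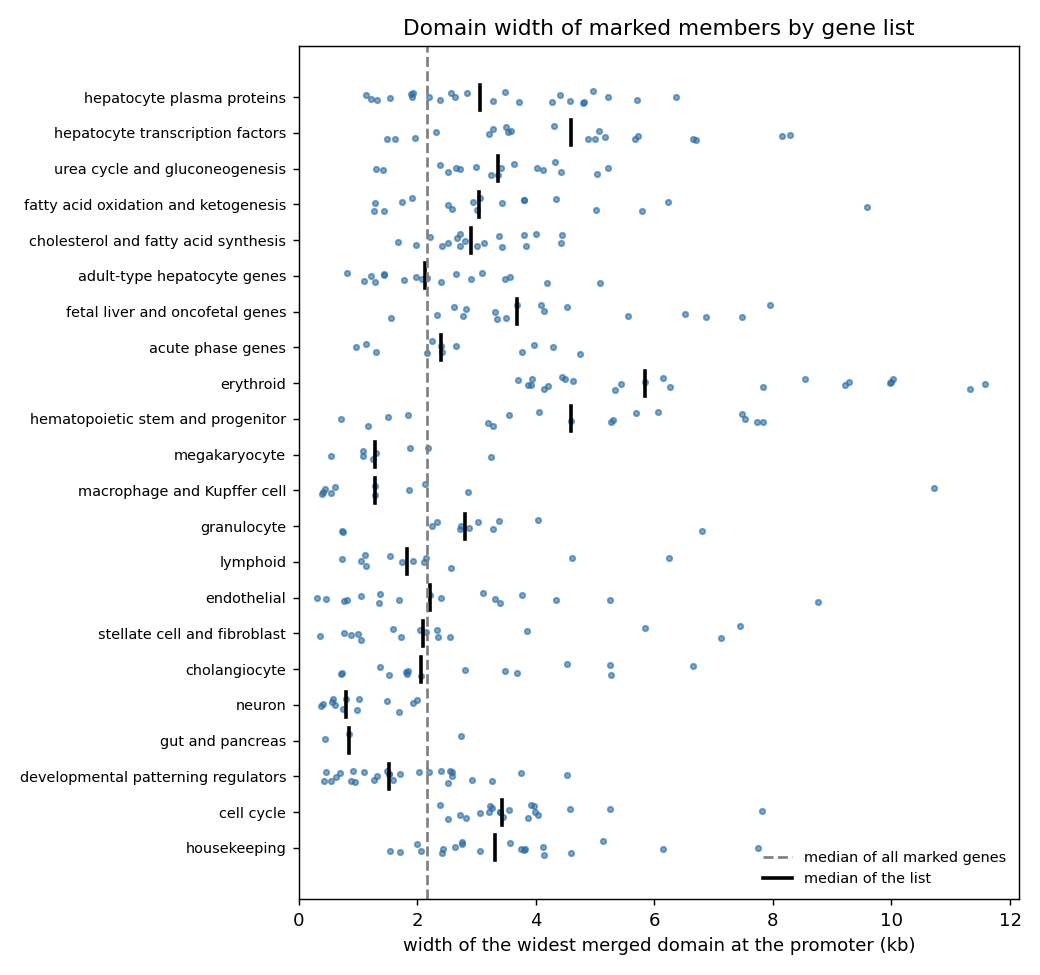
Width of the widest merged domain (kb, horizontal axis) at each marked member of a gene list, with a point per gene and a black bar for the list's median. The dashed line is the median of all marked genes (2170 bp). Erythroid genes lie above it throughout, with a median of 5847 bp.

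Newborn liver is still a site of blood formation, and the hepatocyte lists were set against the blood lists. All 44 hepatocyte genes (plasma proteins and transcription factors) were marked, and 83 of 113 blood genes (73.5%). The blood genes pool lists of unlike share, with 23 of 23 erythroid and 17 of 18 stem and progenitor genes marked against 8 of 16 megakaryocyte, 11 of 20 macrophage, 12 of 17 granulocyte and 12 of 20 lymphoid genes, and the hepatocyte side leaves out the adult-type list (18 of 26). The difference of 26.5 percentage points passed Fisher's exact test (two-sided, p = 2.09e-05, over genes and not animals). It was not adjusted for CpG content. With the same CpG content, random lists were marked at a mean of 50.1% for the hepatocyte and 42.2% for the blood genes. Both observed shares stood at percentile 100. The difference was also seen in each replicate, with 100% against 75.2% in replicate 1 and 100% against 77.0% in replicate 2. The median domain was 3558 bp at hepatocyte genes and 3270 bp at blood genes, a difference of 288 bp that was 996 bp with no merging and 867 bp without replicate 2. The blood median pools unlike widths, from 1278 bp at megakaryocyte and 1279 bp at macrophage genes to 4595 bp at stem and progenitor and 5847 bp at erythroid genes, and the erythroid median lay above those of both hepatocyte lists (3052 and 4594 bp).

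The share of marked genes followed the CpG content of the promoter. In the lowest tertile of the CpG observed to expected ratio 22.0% of 7304 genes were marked, in the middle tertile 78.7% of 7303 and in the highest 98.4% of 7304. The median fold of marked genes was 13.3, 26.2 and 41.6 in the same order. In replicate 1 alone the shares were 22.8%, 80.5% and 98.8%, and in replicate 2 alone 23.3%, 79.7% and 98.7%.

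Promoters that carried a peak in only 1 replicate were few and weak. Replicate 1 had 251 such genes, of which 190 had a −log10 q of at least 2 and 46 of at least 5, and replicate 2 had 225, 147 and 19. Their median fold was 3.65 in replicate 1 and 3.32 in replicate 2, against 30.3 and 29.5 at promoters marked in both. The strongest in replicate 1 were Tmem88b (27.2), Foxq1, Lmntd2 (25.3), Tsks (20.4) and Cldn11 (7.43), and in replicate 2 1700017N19Rik (37.6), Hist1h1d (8.96), Akr1c19 (7.39), Crhr1 (6.26) and Gm14403 (5.16). At Tmem88b, Lmntd2, Tsks, Foxq1, 1700017N19Rik and Hist1h1d the other replicate had a peak between 1 and 187 bp outside the 1 kb window. At Cldn11, Akr1c19, Crhr1 and Gm14403 its nearest peak was 48421, 32516, 96736 and 31901 bp away.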

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

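The scaffold peaks were singled out after their number was seen. Peaks were also present in sequence that the comparisons leave out. Of the replicated peaks, 10 lay on 5 scaffolds that are not placed on chromosomes. This is above the limit of 3 that a count of 0 allows, but no count of 0 was predicted, so it shows only that such peaks are listed. They were 0.0415% of all replicated peaks and had a median fold of 6.69; the lowest was 3.27. The group holds 2 samples, too few for a test of outlying samples.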

How the results depend on the processing

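The CpG ratio over all starts, peaks of 1 gene only and genes with at least 90% unique 31-mers were alternatives chosen after seeing the data. Of 409 values under an alternative, 345 counted as kept. They kept their direction and their side of the threshold, stayed within the spread or, for counts, within a ratio of 1.5. Among them, 249 were marked shares of single lists, where a list called in neither setting also counts as kept. For the values not kept the cause was not tested, unless the setting itself narrows the peaks or genes counted. Sharing between replicates was 78.0% and 76.2% with an overlap of 50% of the peak, 86.1% and 84.9% with −log10 q of at least 2, and 90.7% and 93.2% with at least 5. The rank correlation of strength was 0.852 with −log10 p and 0.863 with −log10 q of at least 2. The promoter share of peaks was 62.8% with a window of 500 bp, 71.6% with 2500 bp, 68.9% with −log10 q of at least 5, 53.4% at the outermost start, 55.1% in the pooled list and from 55.9% to 57.2% without a replicate. The number of marked genes lay between 13722 and 14896 under each alternative. The highest minus the lowest CpG tertile was 77.3 points with a 1 kb CpG window and 82.8 with all starts. Promoters of 1 replicate numbered 46 and 19 with −log10 q of at least 5. The hepatocyte minus blood difference in marked share passed the test under each alternative run (exact p from 5.30e-06 to 0.000450), and the difference in width was 996 bp with no merging, 568.5 bp with a 3 kb gap and from 476 to 866.5 bp without a replicate.

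Calls of marked share were lost for fetal genes at the outermost start (88.2%), for stem and progenitor genes with receptors left out of the background (94.4%) or among unique genes (94.1%), for fatty acid oxidation with peaks of 1 gene only (77.8%), and for fatty acid oxidation and the urea cycle among unique genes (100% each, with fewer genes tested). The share of other genes was 71.1% with receptors left out and from 75.4% to 75.5% among unique genes, against 66.4% in the main setting. Calls were gained for endothelial genes with the 2500 bp window (90%), the pooled list (95%) and peaks of 1 gene only (85%), for stellate genes with the pooled list (90%) and peaks of 1 gene only (80%), and for patterning regulators with 2500 bp (87.5%), the pooled list (96.9%) and peaks of 1 gene only (84.4%). With peaks of 1 gene only, the shares of these lists were unchanged, and that of other genes fell to 54.1%. Without a replicate the share was 90% both times for endothelial genes and from 84.4% to 93.8% for patterning regulators. Lists never called changed sides of the other genes: with receptors left out, adult-type (69.2%), acute phase (70.6%) and granulocyte genes (70.6%), granulocyte genes also with −log10 q of at least 5 (64.7%) and at the outermost start (58.8%), and neuron genes with 2500 bp (70%), the pooled list (75%), peaks of 1 gene only (65%) and from 60% to 75% without a replicate.

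Width percentiles with no merging were 0.06 for macrophage, 49.5 for granulocyte, 41.8 for stellate and 59.9 for cholangiocyte genes, and with a 3 kb gap 94.3 for lipid synthesis, 97.7 for endothelial and 65.4 for patterning genes, which turned from narrow. Without a replicate they ran from 7.87 to 51.8 for macrophage, 97.2 to 97.6 for granulocyte, 27.9 to 50.2 for stellate, 58.4 to 74.7 for cholangiocyte, 0.755 to 65.3 for gut and pancreas, 0.455 to 3.87 for patterning and 0.38 to 1.58 for olfactory receptor genes. Over their 11 alternatives, exact adjusted p ran from 0.000259 to 0.0577 for the urea cycle, 0.00164 to 0.0790 for fatty acid oxidation, 0.00242 to 0.0737 for fetal, 0.00744 to 0.142 for stem and progenitor, 0.0118 to 0.316 for endothelial, 0.0393 to 0.831 for stellate and 0.000495 to 0.364 for patterning genes. No paired analysis was possible because the series holds 1 group. Library size is unknown, and sharing of weak peaks rests on few reads.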

Other observations

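The gene groups in the next 2 paragraphs were chosen after their values were seen. The adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt carried replicated promoter peaks, with folds of 5.89, 9.37, 6.87 and 7.85. The embryonic globin genes Hba-x, Hbb-y and Hbb-bh1 and the globin gene Hbb-bh2 had none. The adult genes had at most 63.7% unique 31-mers, so their levels are uncertain, while the globin genes without a peak had 96.3% or more. Of 39 Hox genes 31 were marked, with a median fold of 7.80: all 11 of cluster a, 8 of 10 of cluster b, 5 of 9 of cluster c and 7 of 9 of cluster d. The highest was Hoxa1 (26.8).

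Among long non-coding RNAs, peaks lay at the starts of Xist (15.5), H19 (12.9), Meg3 (11.8), Kcnq1ot1 (28.1), Airn (18.5) and the snoRNA host gene Gas5 (40.6). Peaks of 8134 and 8980 bp lay at Malat1 and Neat1. Hotair, Rian and Mirg had none. All 49 genes of the mitochondrial large ribosomal subunit were marked, as were 38 of 39 proteasome subunits and 73 of 76 cytosolic ribosomal proteins. None of 35 bitter taste receptor genes was marked, and 1 of 326 vomeronasal receptor genes was, Vmn1r4, at a peak shared with Nt5c3. None of 22 major urinary protein genes was marked, with a median of 9.11% unique 31-mers. By chromosome, the marked share ran from 2.19% of 183 genes on Y, 48.4% of 948 on X and 53.7% of 902 on chromosome 14 to 80.1% of 643 on chromosome 12.

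The 3 patterns below were noticed in the data, and the bound for each test was set before its result was seen. No biological explanation was tested, because the series holds 1 group, and each reading is a hypothesis. The wide domains at erythroid, stem and progenitor, and hepatocyte regulator promoters could come from merging of separate peaks, from stronger enrichment or from domains shared with a neighbouring gene. With no merging, among lists matched on decile of fold, and among genes alone in their domain, the lowest percentile of the 3 lists was 100 each time. Among genes alone in their domain the medians were 5645 bp for 20 erythroid, 4326 bp for 16 stem and progenitor and 3944 bp for 18 regulator genes. The decile of fold was that of a gene's strongest promoter peak, which can lie outside its widest domain. The number of starts per gene was not matched. These tests argue against merging and shared domains as the whole cause, and against enrichment only as measured at the strongest peak. The mix of cell types stays open.

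Adult-type and acute phase genes without a promoter peak may lack one because reads shared between paralogs were lost, or because their promoters are poor in CpG. The 13 unmarked members had a median of 77.4% unique 31-mers, between the bounds of 50% and 90%, and 4 of them had at least 90%, so this test leaves lost reads open. The 30 marked members had more unique sequence, with a median of 98.2%, and 27 of them had at least 90%. The median CpG ratio of the unmarked members was 0.114, against 0.204 in the 30 marked members, a difference of -0.0897 (permutation test, two-sided, p = 0.0340, not adjusted for other tests). That is consistent with low CpG content as a contributor, but paralogy and developmental timing were not separated from it.

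Plasma protein promoters had a lower enrichment than erythroid promoters, with median folds of 13.3 and 29.4, a difference of 1.15 on the log2 scale. This pair of lists was chosen from 25 after the folds were seen, so the p-values here are not adjusted for that choice, and neither median lay in the outer 2.5% of random lists with the same CpG content (percentiles 18.2 and 86.6). Within the lowest CpG tertile the difference was 0.75 (13 erythroid and 17 plasma protein genes, permutation p = 7e-05), and among genes with at least 90% unique 31-mers it was 1.12 (21 and 23 genes, permutation p = 1e-05, the smallest the permutations can give). Both stayed above the bound of 0.5. CpG content and uniqueness were taken around the outermost start, while the fold can come from a peak at another start. These tests therefore argue only against CpG content or repeated sequence near the outermost start as the whole cause of this difference. The share of each cell type in the tissue could not be tested.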
